A study of Mus musculus with 4 samples.

How the data were processed

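RNA-seq was measured in 4 libraries of Treg cells sorted from mouse spleen, 2 WT and 2 Nsd2 cKO, each from RNA of at least 3 mice per the labels' protocols. The groups and replicate numbers came from the labels. The authors deposited RPKM values (reads scaled by transcript length and by the reads of the library) for RefSeq transcripts, without a header that names the unit; the unit was read from the values. HISAT2, DESeq2 and the mm10 build are named in the submitters' processing notes, with no version and no role, and the counting tool and any filter on rows are not given in the sources used here. The deposited listing held 0 rows at 0 in all libraries, so it appears limited to transcripts with a value. How reads over overlapping transcripts, near-identical copies and the transcripts of 1 gene were divided, and whether strand was used, is not given in the sources used here, so values of such features are uncertain.

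Low values moved in steps of whole reads. Of 8314 values between 1 and 20 reads, 61.1% lay within 0.1 of a whole read, where chance gives 20%. These used transcript lengths from GENCODE M21, which are not always those of the RefSeq version in the files. The depth had been set from 1398 transcripts chosen for such steps, which were scored too. The excess over chance therefore partly restates that choice. The depth from these steps was 19150000 to 21267000 reads per library, which limits the precision of transcripts under 1 RPKM. RPKM sums were 430396, 425786, 437436 and 436104 for WT replicates 1 and 2 and cKO replicates 1 and 2. Replicates were compared before use: the median squared difference relative to counting noise was 4.67 in the WT pair and 6.10 in the cKO pair, where counting noise alone gives 0.45, so neither pair looked like 1 library deposited again.

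Of 19291 transcript rows, 16717 were matched to a gene by accession and 1405 by the name in the file, using an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 names. The 1169 rows with no gene name held 10.9% of the RPKM sum and stayed out of the tests. For each of 14220 genes the transcript with the highest mean was used, and 10709 genes with a mean of at least 1 RPKM were tested.

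The design fixed before the data were examined assumed read counts and a count-based test. Since the values are RPKM, the main test was limma (version 3.58.1, R 4.3.3) on log2(RPKM + 1), two-sided, with trend and robust moderation, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. The planned changes of scaling, filter, block, left-out library and fold threshold were run in this fit. Ratios and means in the text are of RPKM itself. Gene lists, 28 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the 27 lists with a tested member; the neutrophil and mast cell list had none. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, so a list passes less easily whatever its correlation. Adjustment over a list alone makes no allowance for the number of lists. P-values measure the spread between pools of RNA, which may be partly technical. The figures were drawn with matplotlib 3.10.9, and tables were read with Python 3.11.15 and pandas 2.3.3.

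The genes named were fixed by a rule before the data were examined. It took Nsd2, up to 10 genes per direction past the threshold or otherwise the 5 of lowest unadjusted p with separated groups, 7 genes always named (Foxp3, Il2ra, Ctla4, Ikzf2, Cxcr4, Nsd1 and Nsd3), and up to 4 genes of lowest p from each list with at least 5 tested members. The level it required was set at a mean of 4 RPKM in place of a value on the count scale, and was applied to the genes past the threshold or of lowest p over all genes, and not to the genes always named or taken from lists. Lists that were not called, other than the Treg signature and the chemokine receptors, were limited to 2 genes after the values were seen. The values of 1 gene that the rule names are not reported here.

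The scripts were tested on simulated data for this comparison, with 10709 genes, 200 of them changed, in 5 simulations. With a difference between replicate numbers like the one in the data and no block, 0% of 1.5-fold, 17.2% of 2-fold and 92.8% of 4-fold changes were recovered, with a mean of 0.2 false calls. With the replicate number as a block on the same simulated data, 72.7%, 95.4% and 99.4% were recovered, with a mean of 15.2 false calls. Without such a difference, 70.7%, 95.7% and 100% were recovered, with a mean of 6 false calls. Camera called the changed list in 5 of 5 simulations and 0 of 135 unchanged lists. Noise was drawn independently for each gene and the unchanged lists were random genes. The result therefore does not show how often camera calls a list of correlated genes. All members of the changed list differed by 1.5-fold to 4-fold, and smaller shifts were not simulated. A first version of the simulation added counting noise to spread estimates that already held it; it was corrected for that reason.

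GC content and length were taken from GENCODE M21 transcripts by accession without version, then by gene symbol, for 97.4% of the tested genes. A first match by accession with version covered 76.4%, too few for the check, and was replaced. The correction removed a spline trend in both properties from each library.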

Results

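The data were RNA-seq profiles of regulatory T (Treg) cells sorted from the spleens of C57BL/6 mice. Treg cells are the Foxp3-expressing T cells that restrain immune responses. There were 2 libraries from wild-type (WT) mice and 2 from mice with a conditional knockout (cKO) of Nsd2 in Treg cells. Nsd2 is a histone methyltransferase that writes dimethylation on lysine 36 of histone H3. Each library held RNA pooled from at least 3 mice, so the spread between libraries was a spread between pools. Reads were 50 nt and single-ended. The deposited values were RPKM for 19291 transcripts in each library. The depth that the steps between low values gave was 19515000 reads for WT replicate 1, 19150000 for WT replicate 2, 19228000 for cKO replicate 1 and 21267000 for cKO replicate 2. At these depths 1 RPKM on a 2 kb transcript stood for 38.3 to 42.5 reads. The design implied 1 comparison, cKO against WT, which asks what the transcriptome of splenic Treg cells looks like without Nsd2.

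The targeted gene, listed under its older symbol Whsc1 (GRCm38 chromosome 5, 33820676 to 33897966), was lower in both cKO libraries. Nsd2 stood at 6.82 and 7.44 RPKM in the WT libraries and at 3.46 and 4.27 RPKM in the cKO libraries. The means were 7.13 ± 0.439 RPKM in WT and 3.86 ± 0.573 RPKM in cKO (SD, n = 2 each), and the cKO mean was 54.2% of the WT mean. Of the 3 Nsd2 transcripts in the files, NM_001081102.2 stood at 54.2% of WT and NM_001177884.1 at 61.6%. The values of NM_001081102.2 were nearly identical to those above in every library, so they are not a separate measurement. The log2 fold change on the log2(RPKM + 1) scale was -0.74 with a standard error of 0.15. It was -0.81 between the libraries numbered 1 and -0.68 between those numbered 2. The labels do not say which exons the deletion removes, so reads over the remaining exons may count toward these values. The difference did not pass the limma test over all genes (unadjusted p = 0.00308, adjusted p = 0.9998), and among the settings run for this gene it passed only without cKO replicate 2, where the log2 fold change was -0.86 and limma's adjusted p was 0.0485.

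The genes with the lowest p on the lower side included a chemokine receptor and a cytokine receptor. Cxcr4, the receptor for the chemokine Cxcl12 (GRCm38 chromosome 1, 128588199 to 128592299), stood at 102 and 94.6 RPKM in WT and at 48.1 and 40.2 RPKM in cKO. Its mean was 2.22-fold lower in cKO (98.2 ± 5.12 against 44.2 ± 5.55 RPKM, SD, n = 2). Il7r, the alpha chain of the interleukin 7 receptor (chromosome 15, 9506159 to 9529941), stood at 94.2 and 98.9 RPKM in WT and at 33.6 and 47.7 RPKM in cKO, a 2.37-fold lower mean. Tsc22d3, a glucocorticoid-induced transcription regulator, was at 128 ± 3.97 RPKM in WT and 78.4 ± 7.43 RPKM in cKO (SD, n = 2). Phlpp1, a phosphatase that acts on Akt, was at 8.82 ± 0.697 and 4.99 ± 0.108 RPKM (SD, n = 2), and Ston1, an endocytic adaptor, at 12.4 ± 5.07 and 3.43 ± 0.809 RPKM (SD, n = 2).

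On the higher side, the genes with the lowest p were Tmem160, Plac8, Scd2, Tspoap1 and Il1r2. Plac8 stood at 3.90 and 2.48 RPKM in WT and at 10.7 and 8.11 RPKM in cKO, a ratio of 2.95. Il1r2, the decoy receptor for interleukin 1, was at 5.61 ± 0.157 RPKM in WT and 10.6 ± 1.51 RPKM in cKO (SD, n = 2). Scd2, a fatty acid desaturase, was at 17.5 ± 0.518 and 28.5 ± 0.264 RPKM (SD, n = 2). Tmem160 was at 17.4 ± 0.127 and 29.2 ± 1.48 RPKM (SD, n = 2), and Tspoap1 at 2.74 and 2.50 RPKM in WT and 8.50 and 5.67 RPKM in cKO. Within numbers 1 and 2 the log2 fold changes were -1.07 and -1.21 for Cxcr4, -1.46 and -1.04 for Il7r, and 1.25 and 1.39 for Plac8; their shared sign followed from the choice of genes with separated groups.

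No gene passed the test across all genes. Of 10709 genes tested with limma, 0 had an adjusted p under 0.05, and 332 had an unadjusted p under 0.05 where 535 would be expected by chance if the libraries differed in nothing else. They also differed by replicate number, which this fit does not model and which adds to the spread within groups. For Cxcr4, the gene of lowest p, limma gave an unadjusted p of 0.000256 and an adjusted p of 0.9998. Both cKO libraries lay above both WT libraries for 1860 genes and below them for 970, which together were 26.4% of the genes where chance gives 33.3%. Among these, 180 genes were at least 1.5-fold higher and 82 at least 1.5-fold lower by their means. At a 2-fold difference the numbers were 37 higher and 22 lower. Leaving out 1 library gave 66 genes without WT replicate 1, 40 without WT replicate 2, 21 without cKO replicate 1 and 65 without cKO replicate 2, in fits where 1 group had a single library that was assumed to vary like the other group and where the replicate numbers were unbalanced.

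**Figure D1:**
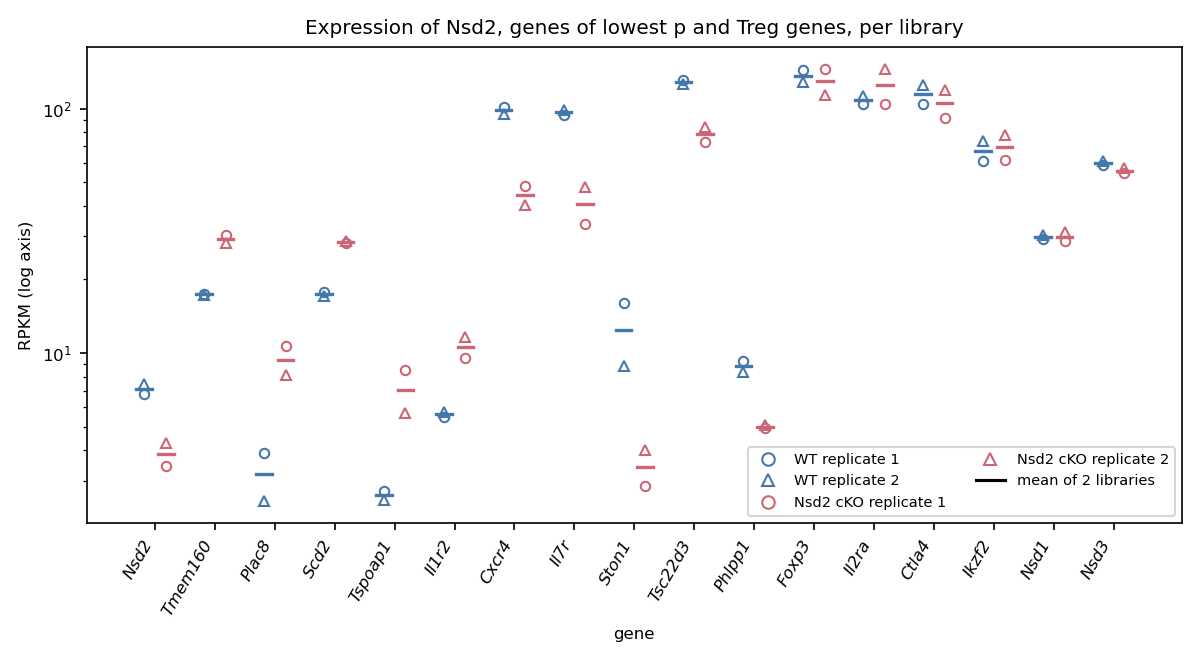
RPKM (log axis) of Nsd2, the 10 genes of lowest p and 6 further genes named in advance, one point per library, with WT in blue, Nsd2 cKO in red, circles for replicate 1, triangles for replicate 2 and bars for the means of 2 libraries. Cxcr4 lies between 40.2 and 48.1 RPKM in the cKO libraries and between 94.6 and 102 RPKM in the WT libraries, whereas the points of Foxp3 overlap.

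The ranges of Foxp3, Il2ra, Ctla4 and Ikzf2, which mark Treg cells, overlapped between genotypes. Foxp3, the lineage-defining transcription factor, was at 136 ± 11.2 RPKM in WT and 129 ± 22.6 RPKM in cKO (SD, n = 2). Il2ra, the alpha chain of the interleukin 2 receptor, was at 108 ± 5.78 and 125 ± 29.4 RPKM, and Ikzf2, which encodes Helios, at 67.2 ± 8.91 and 69.7 ± 11.3 RPKM (SD, n = 2 each). Ctla4, an inhibitory receptor, stood at 105 and 125 RPKM in WT and at 91.9 and 119 RPKM in cKO. For each of these 4 genes the difference was smaller than the larger SD, and its sign changed when single libraries were left out. Both the SD and the left-out fits take in the difference by replicate number. Within numbers 1 and 2 the log2 fold changes were -0.187 and -0.073 for Ctla4 and 0.019 and 0.078 for Ikzf2. They were 0.015 and -0.174 for Foxp3 and -0.0045 and 0.37 for Il2ra. Of the 21 genes of the Treg signature list, 13 had a log2 fold change above 0 and 0 passed when adjusted over the list alone. Itgae, the integrin chain CD103, was at 16.3 ± 2.04 RPKM in WT and 27.1 ± 2.38 RPKM in cKO, and Il2rb at 342 ± 12.2 and 288 ± 2.19 RPKM (SD, n = 2). The related methyltransferases Nsd1 (29.9 ± 0.766 and 29.9 ± 1.87 RPKM) and Nsd3 (59.8 ± 1.48 and 55.7 ± 2.04 RPKM, SD, n = 2) had log2 fold changes with standard errors of 0.12, and both lay within 1 standard error of 0. In the list of writers and erasers of lysine 36 methylation, which holds Nsd1 and Nsd3 and not Nsd2, 7 of 13 genes were above 0, with a median log2 fold change of 0.01 that turned to -0.03 with median-of-ratios scaling.

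Genes of chemokine receptors and homing went both ways. Over the 24 genes tested, 16 had a log2 fold change above 0, and 2 passed when adjusted over the list alone. These were Cxcr4 on the lower side (adjusted p = 0.00615 with limma) and Itgae on the higher side (adjusted p = 0.0372 with limma). This adjustment makes no allowance for the number of lists, and Itgae did not pass within the Treg signature list. Gpr15, a receptor that directs T cells to the large intestine, was at 5.61 ± 0.719 RPKM in WT and 9.71 ± 2.34 RPKM in cKO (SD, n = 2). Ccr4 was at 14.3 ± 0.045 and 18.7 ± 1.31 RPKM (SD, n = 2). In the naive and resting T cell list, 6 of 18 genes were above 0 and Il7r passed when adjusted over the list alone (adjusted p = 0.0127 with limma). The other naive genes differed less, and Igfbp4 was higher in cKO (132 ± 18.6 against 173 ± 32.4 RPKM, SD, n = 2). With camera this list had an adjusted p of 0.0586, and 0.043 with median-of-ratios scaling. It had an adjusted p of 0.526 with an estimated correlation and 0.119 after GC and length correction.

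Cholesterol synthesis was the list with the lowest p. All 19 genes tested had a log2 fold change above 0, with a median of 0.31, and 14 of them were above both WT libraries in both cKO libraries. Fdps, which makes farnesyl diphosphate, was at 12.4 ± 0.313 RPKM in WT and 18.2 ± 0.272 RPKM in cKO (SD, n = 2). When adjusted over the list alone, 2 genes passed, Fdps among them (adjusted p = 0.0448 with limma), and 0 passed over all genes. Sqle, the squalene epoxidase, was at 5.66 ± 0.674 and 8.94 ± 1.83 RPKM, and Fdft1, the squalene synthase, at 6.17 ± 0.339 and 8.31 ± 0.884 RPKM (SD, n = 2). The list was called higher by camera with a preset correlation of 0.01 (adjusted p = 2.03e-09). This call was lost with an estimated correlation of 0.122 (camera's unadjusted p = 0.0583, adjusted p = 0.526). At the preset it was kept with the replicate block (camera's adjusted p = 2.46e-08) and after GC and length correction (2.31e-10). Of the 7 lists called, only this one kept its call whichever single library was left out. These settings all rest on the preset correlation. The estimated correlation of the other lists called was 0.222 for cell cycle, 0.216 for B cell markers and 0.199 for effector Treg genes. It was 0.154 for immediate early and stress genes, 0.0473 for oxidative phosphorylation and -0.0282 for the interferon response. Where it exceeds the preset of 0.01, p-values at the preset may be too low. Both this and the 2 residual degrees of freedom may enter the loss of those calls.

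Effector Treg genes were higher as a list under the preset correlation. Of 22 genes, 19 had a log2 fold change above 0, the median was 0.20, and 0 passed when adjusted over the list alone. Gzmb, a cytotoxic granule protease, was at 4.38 ± 0.096 RPKM in WT and 6.66 ± 0.080 RPKM in cKO (SD, n = 2). S100a4 was at 22.6 ± 5.64 and 37.1 ± 8.59 RPKM, and Fgl2, a secreted mediator of suppression, at 6.45 ± 0.486 and 8.35 ± 0.011 RPKM (SD, n = 2 each). Lgals1, which encodes galectin-1, had a cKO mean 1.48 times the WT mean. Camera gave an adjusted p of 0.00106, which became 0.526 with an estimated correlation, 0.126 without WT replicate 2 and 0.0859 without cKO replicate 1. The B cell markers were also higher as a list and lost their call without the same libraries. Both omissions unbalance the replicate numbers in the same direction, so the shared loss cannot tell a link between the lists from a difference by number. C1qb, a macrophage marker, was highest in cKO replicate 1.

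Cell cycle genes followed a like pattern, with 27 of 29 above 0, a median log2 fold change of 0.19 and 0 genes passing when adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, was at 5.78 ± 0.558 RPKM in WT and 8.01 ± 0.036 RPKM in cKO (SD, n = 2). Top2a, the topoisomerase of dividing cells, had a log2 fold change of 0.34 with a standard error of 0.14. Birc5 was at 5.03 ± 0.029 and 6.36 ± 0.373 RPKM, and Ube2c at 7.46 ± 1.82 and 9.76 ± 0.768 RPKM (SD, n = 2). Camera called the list higher (adjusted p = 0.00026), with an adjusted p of 0.526 with an estimated correlation, 0.0538 without WT replicate 2 and 0.312 without cKO replicate 2.

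Among the 26 type I interferon response genes, 23 were above 0, with a median log2 fold change of 0.13 and 0 passing when adjusted over the list alone. Isg15, a ubiquitin-like protein induced by interferon, was at 14.0 ± 0.478 RPKM in WT and 17.6 ± 0.792 RPKM in cKO, and Irf7 at 27.4 ± 3.01 and 33.7 ± 3.77 RPKM (SD, n = 2). Mx1 was at 2.39 ± 0.307 and 3.45 ± 0.052 RPKM, and Mx2 at 1.11 ± 0.226 and 1.67 ± 0.299 RPKM (SD, n = 2). The camera call (adjusted p = 0.0023) was lost with an estimated correlation (adjusted p = 0.526) and when any single library was left out. The estimated correlation was -0.0282, below the preset, so correlated members do not account for the first loss.

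Of 46 nuclear genes of oxidative phosphorylation, 43 were above 0, with a median log2 fold change of 0.11 and 0 passing when adjusted over the list alone. Ndufb10, a subunit of complex I, was at 58.4 ± 2.22 RPKM in WT and 67.2 ± 1.38 RPKM in cKO, and Atp5g1, a subunit of the ATP synthase, at 36.8 ± 2.05 and 42.2 ± 2.69 RPKM (SD, n = 2). Uqcrh was at 107 ± 1.99 and 121 ± 2.35 RPKM, and Uqcr10 at 53.8 ± 10.2 and 66.2 ± 12.1 RPKM (SD, n = 2). Camera gave an adjusted p of 0.000944, which became 0.526 with an estimated correlation and 0.337 after correction of each library for GC content and transcript length. The call was lost without WT replicate 2 and without cKO replicate 1, as was that of the B cell markers. Both omissions unbalance the replicate numbers in the same direction. The shared loss therefore cannot tell a link between the lists from a difference by number.

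Immediate early and stress genes were the list called lower. Of 19 genes, 4 were above 0 and 7 lay below both WT libraries in both cKO libraries, with a median log2 fold change of -0.17 and 0 passing when adjusted over the list alone. Dusp1, a phosphatase of mitogen-activated protein kinases, was at 84.4 ± 22.8 RPKM in WT and 54.8 ± 1.96 RPKM in cKO, and Fosl2, an AP-1 subunit, at 2.56 ± 1.36 and 0.998 ± 0.244 RPKM (SD, n = 2). The heat shock genes Hsph1 and Hspa8 were highest in WT replicate 2. Hsph1 stood at 40.1 RPKM in WT replicate 1, 104 in WT replicate 2, 32.9 in cKO replicate 1 and 23.3 in cKO replicate 2. Hspa8 stood at 887 and 1197 RPKM in WT and at 751 and 677 RPKM in cKO. Camera gave an adjusted p of 4.4e-06, which became 0.526 with an estimated correlation and 0.111 without cKO replicate 2.

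Several markers of other cell types were measured in both genotypes. Of 20 B cell markers, 6 were tested and all 6 were above 0, with a median log2 fold change of 0.23 and 0 passing when adjusted over the list alone. Cd79b, a chain of the B cell receptor complex, was at 4.89 ± 0.942 RPKM in WT and 7.59 ± 0.628 RPKM in cKO (SD, n = 2). Cd79a was at 1.09 ± 0.316 and 1.57 ± 0.270 RPKM, Cd22 at 1.64 ± 0.066 and 2.11 ± 0.268 RPKM, and Cd74 at 26.8 ± 2.63 and 30.2 ± 0.736 RPKM (SD, n = 2 each). Camera called the list higher (adjusted p = 0.0071), with an adjusted p of 0.526 with an estimated correlation, 0.391 without WT replicate 2 and 0.464 without cKO replicate 1. The myeloid and dendritic cell markers stood apart in cKO replicate 1, where C1qb was at 4.90 RPKM against 1.35, 2.36 and 1.64 RPKM in WT replicate 1, WT replicate 2 and cKO replicate 2. Csf1r was at 3.07 RPKM in cKO replicate 1 and at 0.860, 1.48 and 0.971 RPKM in the same 3 libraries. Of the CD8 T and NK cell markers, 5 of 7 were above 0, and Ccl5, a chemokine of effector T cells, was at 5.97 ± 1.78 RPKM in WT and 10.1 ± 2.43 RPKM in cKO (SD, n = 2). The numbers above 0 were 9 of 11 for myeloid and dendritic cells, 6 of 6 for erythroid cells and platelets, 1 of 2 for plasma cells, 2 of 2 for stroma and endothelium and 2 of 4 for sex-linked genes. Without cKO replicate 1, camera's direction was lower for the myeloid and erythroid lists, and without cKO replicate 2 it was higher for both. With all 4 libraries the estimated correlation was 0.559 for the myeloid and 0.924 for the erythroid list, far above the preset of 0.01. Members of each list thus moved together and are not separate evidence. Camera's adjusted p for the lists in this paragraph other than the B cell markers ran from 0.148 to 0.959 with all 4 libraries. Of their genes, 0 passed when adjusted over the list alone.

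**Figure D2:**
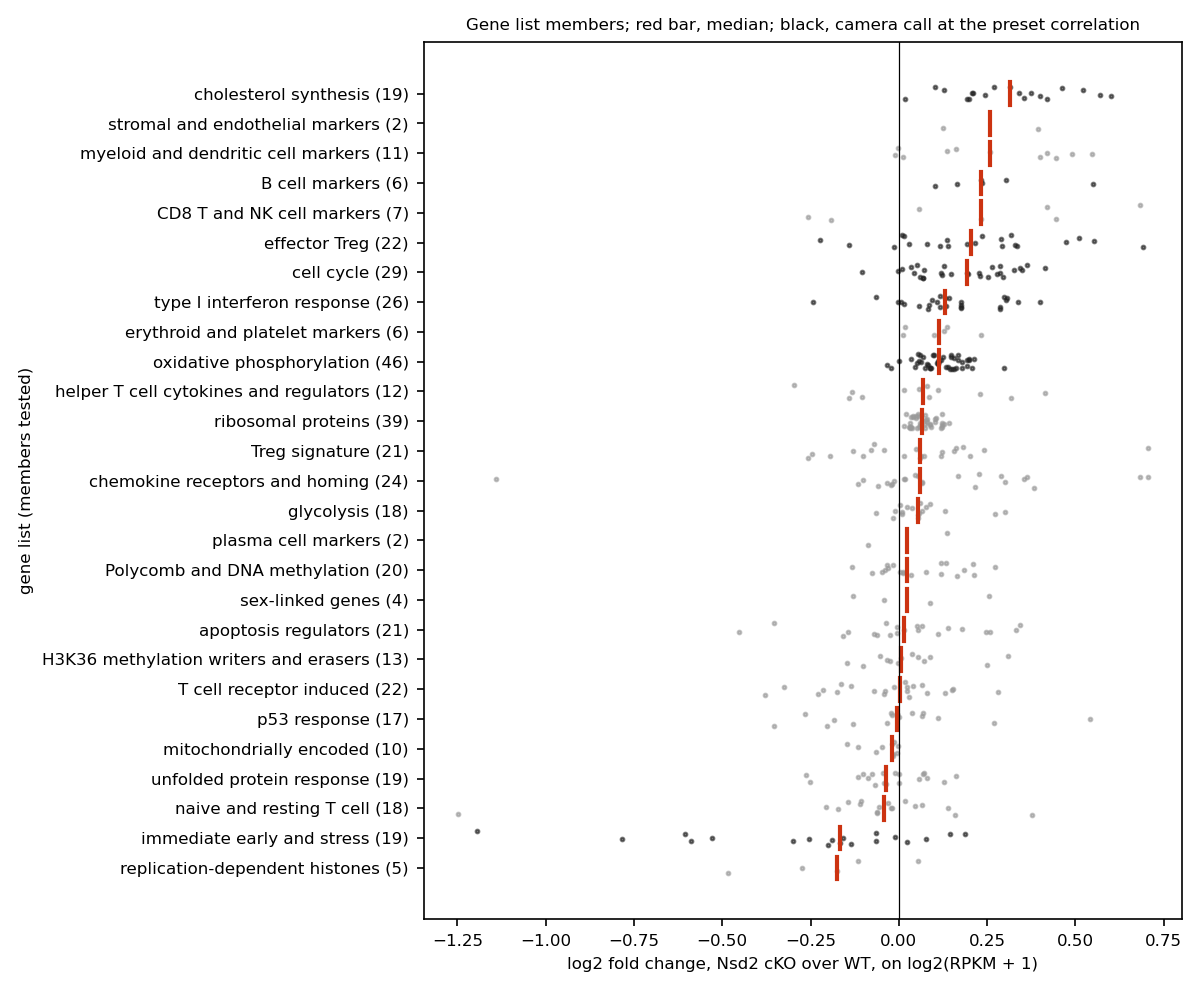
Log2 fold change of each tested member (points) of the 27 gene lists with at least 1 tested member, cKO over WT, with the list's median as a red bar and black points for the lists that camera called at the preset correlation. The median was 0.31 for cholesterol synthesis and -0.17 for immediate early and stress genes. No call held with an estimated correlation, where the test has 2 residual degrees of freedom.

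The remaining lists were not called. Of the helper T cell cytokines and regulators, 8 of 12 were above 0; Tnf was at 14.3 ± 1.30 RPKM in WT and 19.4 ± 0.131 RPKM in cKO, and Bcl6 at 9.92 ± 0.291 and 7.90 ± 0.499 RPKM (SD, n = 2). Genes induced by the T cell receptor were split, with 11 of 22 above 0, and Cd69 was at 44.9 ± 2.83 and 34.7 ± 7.94 RPKM (SD, n = 2). Among 21 apoptosis regulators, 11 were above 0, and Bcl2l11, which encodes the pro-apoptotic protein Bim, was at 21.4 ± 0.832 RPKM in WT and 15.4 ± 0.561 RPKM in cKO (SD, n = 2). The cell cycle inhibitor Cdkn1a was at 0.758 ± 0.010 and 1.58 ± 0.460 RPKM (SD, n = 2) in a p53 response list with 7 of 17 genes above 0. The numbers above 0 were 15 of 18 for glycolysis, 8 of 19 for the unfolded protein response, 13 of 20 for Polycomb and DNA methylation, 1 of 5 for replication-dependent histones, 39 of 39 for ribosomal proteins and 0 of 10 for mitochondrially encoded genes. Camera's direction for the last 2 depended on the libraries, and leaving 1 out unbalances the replicate numbers. It was higher for the mitochondrially encoded genes without WT replicate 2 and without cKO replicate 1, and lower without either of the other 2. The estimated correlation of these genes was 0.993, against the preset of 0.01, so they are not separate evidence. The ribosomal proteins turned to lower, not called, without WT replicate 2 (adjusted p = 0.392), without cKO replicate 1 (adjusted p = 0.74) and after GC and length correction (adjusted p = 0.454). Median, mean and camera differed in sign for the genes induced by the T cell receptor (median 0.0022, mean -0.0362, camera lower), and camera gave the lower direction against a median above 0 for the apoptosis regulators, the lysine 36 list and the plasma cell markers. The medians of these 4 lists, of Polycomb and DNA methylation and of the sex-linked genes were below 0 with median-of-ratios scaling. The median log2 fold change of all genes was itself 0.03, against 0.06 for the ribosomal proteins. Camera's adjusted p for these lists ran from 0.0586 to 0.959, and 0 genes of them passed when adjusted over the list alone.

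The libraries differed more by replicate number than by genotype. The first principal component held 57.6% of the variance and separated both libraries numbered 1 from both numbered 2, and the second held 26.0% and separated the genotypes. The correlation of log2(RPKM + 1) across genes, which are not independent replicates, was 0.989 between WT replicate 2 and cKO replicate 2 and 0.984 between WT replicate 1 and cKO replicate 1. It was 0.982 between the WT libraries and 0.976 between the cKO libraries. With limma, 825 genes differed between the numbers in a fit without genotype (476 higher and 349 lower in number 2, adjusted p under the threshold of 0.05), and 2418 in a fit with genotype. Mitochondrially encoded transcripts made up 1.46% and 2.29% of the RPKM sum in the WT libraries numbered 1 and 2, and 1.36% and 2.23% in the cKO libraries. The labels do not say what the numbers mark.

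**Figure D3:**
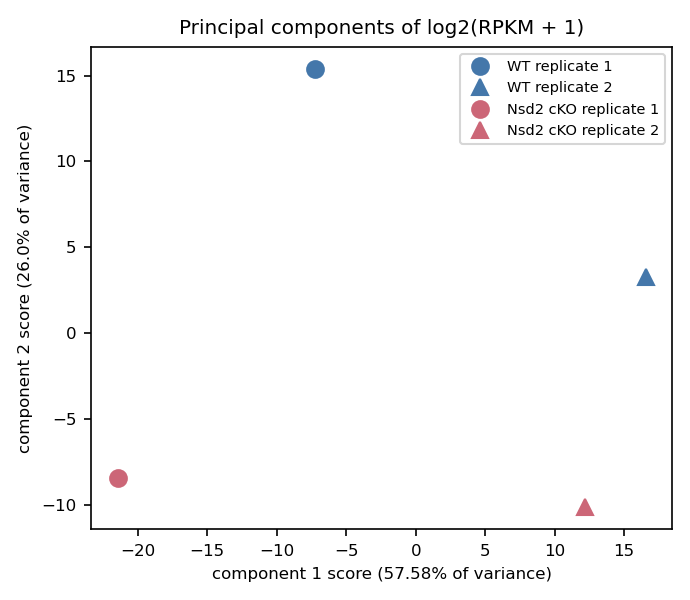
Scores of the 4 libraries on the first 2 principal components of log2(RPKM + 1), with 57.6% and 26.0% of the variance, WT in blue and Nsd2 cKO in red, circles for replicate 1 and triangles for replicate 2. Component 1 separates the replicate numbers and component 2 the genotypes.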

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

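Settings other than the planned scaling, filter, block, left-out library, fold threshold, estimated correlation and fry were chosen after seeing the data. DESeq2, limma-voom and the legacy edgeR fit had been planned for counts and were not run, since the values are RPKM. The gene count was 0 with both other scalings, no filter (599 genes at an unadjusted p under 0.05, of 14220 tested), a stricter filter and a 2-fold threshold. It was also 0 with pseudocounts of 0.1, 0.5 and 4, sums over transcripts, each transcript tested, and trend or robust moderation off singly or together. After GC and length correction it was 0 too (lowest adjusted p = 0.0793 with limma). There 795 of 10432 genes had an unadjusted p under 0.05, against 332 of 10709 in the main fit. The samples share only a number: the labels do not say that it marks a batch, and the deviations of same-numbered libraries correlated across genes at 0.50. With the replicate number as a block, 1 gene, Cxcr4, passed (adjusted p = 0.047 with limma) and 1638 had an unadjusted p under 0.05. That call depended on other settings. With the block, 15 genes passed at a pseudocount of 0.1, 1 at 0.5 and 11 at 4, and 0 after GC and length correction or with trend moderation, robust moderation or both switched off; the cause was not tested. Leave-one-out fits gave 21 to 95 genes, 21 to 66 of them with robust moderation and 28 to 95 without it, the cause not being tested. They had 1 residual degree of freedom, the lone library was assumed to vary like the other group, and they left the replicate numbers unbalanced, so these counts are not read as changes with genotype. The log2 fold change of Nsd2 kept its direction in every setting run, from -0.86 to -0.62 with single libraries left out. Adjusted over each list alone, the blocked fit passed 10 effector Treg, 10 cholesterol synthesis, 9 chemokine receptor and homing and 3 Treg signature genes. Without the block these were 0, 2, 2 and 0, and no other list had more than 2 with it. The blocked fit has 1 residual degree of freedom.

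Of the 27 lists, 7 were called at the preset correlation, 0 with estimated correlations and 0 with fry, which tests a list by itself (lowest adjusted p = 0.29). For most called lists the estimate exceeded the preset, and 2 residual degrees of freedom make any call hard to reach. With the block 8 were called, the ribosomal proteins being added, with single libraries left out 6 to 8, and after GC and length correction 6, or 5 with the block. The lists called changed with the library left out: of the 7, 6 were still called without WT replicate 1, 2 without WT replicate 2, 3 without cKO replicate 1 and 4 without cKO replicate 2. The replication-dependent histones were gained without WT replicate 2 and cKO replicate 1 (adjusted p = 0.0334 and 0.00261 with camera) and the CD8 T and NK cell markers without WT replicate 2 (adjusted p = 0.0334). Leaving out 1 library unbalances the replicate numbers between genotypes, so a difference by number enters the contrast. The mitochondrially encoded share of the RPKM sum differed by number in both genotypes, at 1.46% and 2.29% in WT and 1.36% and 2.23% in cKO. Directions turned as follows when single libraries were left out, other causes not being tested. The log2 fold change ran from -0.26 to 0.10 for Foxp3, -0.058 to 0.42 for Il2ra, -0.31 to 0.053 for Ctla4, -0.11 to 0.21 for Ikzf2, -0.063 to 0.060 for Nsd1, -0.21 to 0.077 for ND4L, -0.58 to 0.29 for ND4, -0.091 to 1.07 for C1qb, -0.12 to 0.92 for Csf1r, -0.12 to 0.39 for Gata1 and -0.23 to 0.43 for Car2. Nsd1 stood at 0.051 after GC and length correction. Camera's adjusted p ran from 2.47e-05 to 0.00601 for mitochondrially encoded genes, 2.1e-10 to 0.879 for myeloid and dendritic cell markers and 1.8e-08 to 0.0538 for erythroid and platelet markers. Each of these 3 lists was called higher in some left-out fits and lower in others. Directions also turned, with no call in either fit, for the Treg signature (0.692 to 0.892), glycolysis (0.32 to 0.804), apoptosis regulators (0.639 to 0.972), the lysine 36 list (0.804 to 1), ribosomal proteins (0.0598 to 0.74), plasma cell markers (0.656 to 0.972) and sex-linked genes (0.0875 to 0.254).

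With all 4 libraries, camera's direction turned under other settings, none called. Helper T cell cytokines and regulators turned with the stricter filter (adjusted p = 0.558) and the block (0.992). After GC and length correction apoptosis regulators (0.871), the lysine 36 list (0.741) and ribosomal proteins (0.454) turned, and with the block added the lysine 36 list (0.846), ribosomal proteins (0.165) and plasma cell markers (0.951). Myeloid and dendritic cell markers turned with the stricter filter (0.819) and erythroid and platelet markers with a pseudocount of 0.1 (0.983). Fry gave the other direction for apoptosis regulators (0.854), the lysine 36 list (0.722) and plasma cell markers (0.854). Of the settings run for each named gene other than Nsd2, only the block and left-out libraries brought a gene past the threshold. The block at a pseudocount of 0.1 or 4 was run only for the count over all genes. Either brought Itgae, Plac8, S100a4, Scd2 and Tmem160 past it, besides Cxcr4. Depth limits mainly genes near 1 RPKM.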

Other observations

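The tests on the glucocorticoid list, the heat shock list and the GC, length, mitochondrial and ribosomal trends had their bounds set before their values were seen, and the tests on depth and on resting T cell genes were chosen after the result was seen. The groups in the next paragraph were also chosen after their values were seen.

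Small nucleolar RNAs, which guide the modification of ribosomal RNA and lie mostly in introns of other genes, had 40 of 64 members above 0 and a median log2 fold change of 0.14. The median of all genes was 0.03. Camera gave a p of 0.00165 for the small nucleolar RNAs, and a p of 0.0899 with an estimated correlation. Over all genes the difference between genotypes fell with transcript length (Spearman's rho -0.256). No value corrected for GC content and length is given here for this group, so that trend cannot be set aside. Snora24 stood at 8.67 and 8.03 RPKM in WT and at 15.2 and 16.3 RPKM in cKO. The V and J segments of the T cell receptor alpha chain had 39 of 61 members below 0, a median of -0.15, and 16 members below both WT libraries in both cKO libraries. Camera gave a p of 8.92e-07, and a p of 0.0372 with an estimated correlation. Traj15 stood at 34.2 and 37.4 RPKM in WT and at 18.2 and 22.7 RPKM in cKO. Of the segments of the beta chain, 22 of 34 were above 0. Camera gave a p of 0.68 for them. Since these groups were picked from the same values, their p-values describe these libraries and do not test the groups independently.

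Cxcr4, Il7r and Tsc22d3 were lower in both cKO libraries. Fewer resting cells in the cKO libraries would lower the other resting T cell genes too. The median log2 fold change of the 17 others was -0.03 with a standard error of 0.03. That speaks only against a large loss of such cells, for which a bound of -0.3 was set after the result. Of the whole list, Il7r included, 12 of 18 genes were below 0, and a median over bulk libraries cannot exclude a small loss. Another candidate explanation is lower transcription of glucocorticoid-induced genes, since these 3 genes are known targets of that receptor. A list of 15 other such genes had a median of -0.175 with a standard error of 0.093, with 12 below 0 and 8 below both WT libraries in both cKO libraries. Camera, run after these values were seen, gave a p of 4.93e-06 for the list and a p of 0.0395 with an estimated correlation, so its genes stood lower than others, but the median lies between the bounds of -0.3 and -0.1, and whether the shift is large enough stays open. Fkbp5 stood at 37.5 and 23.7 RPKM in WT and at 17.2 and 19.3 RPKM in cKO, and a direct effect of Nsd2 on these genes was not tested.

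The libraries deviated together by replicate number across genotypes. Sequencing depth went opposite ways, with number 2 over number 1 at 0.981 in WT and 1.106 in cKO, which argues against depth as the cause. GC content was related to the difference between numbers (Spearman's rho across genes -0.67 in WT and -0.718 in cKO), and length less so (0.221 and 0.211). The difference between genotypes was related to both as well (rho 0.177 for GC content and -0.256 for length). The correlation of same-numbered deviations was 0.506 before GC and length correction and still 0.266 after it. GC and length trends may thus account for part of it and not the whole. The value lies close to the bound of 0.25 (it was 0.351 over the 76.4% of genes first matched by accession with version), and genes are not independent. Without 197 mitochondrial and ribosomal protein genes the correlation was 0.502, and no biological explanation was tested, since the labels give none for the numbers.

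Several heat shock genes were highest in WT replicate 2. Of a further list of 17 heat shock factor targets, 14 were highest there, while Hspb1 and Bag3 were highest in cKO replicate 1 and Hspbp1 in WT replicate 1. The list had a median log2 ratio of 0.647 with a standard error of 0.18 in WT replicate 2 over the mean of the other 3 libraries, which is consistent with a heat shock response in that library. The difference between replicate numbers is less clear as a source: the same list had a median of 0.098 with a standard error of 0.152 in cKO replicate 2 over cKO replicate 1, which decides neither way. The lower stress list in cKO may therefore rest in part on WT replicate 2, and without that library camera gave an adjusted p of 0.0254 for it, with single libraries left out giving 4.96e-11 to 0.111.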
